A study of Lactiplantibacillus plantarum with 12 samples.

How the data were processed

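Total RNA of *Lactiplantibacillus plantarum* WCFS1 was extracted with RNeasy Mini kits, and 1 µg per sample went into TruSeq RNA libraries, per the labels. The submitters' processing notes name bcl2fastq 1.8.4 and Bowtie2, the latter without a version. The deposited table holds FPKM, fragments per kilobase of gene scaled to the mapped fragments of the library, which the authors computed for each library, with no further scaling between libraries stated. The tool that computed FPKM, the genome build, the filters, the strand of the libraries and the handling of reads that match several genes are not given in the sources used here. Genes with near-identical copies are therefore uncertain, and an antisense transcript could not be told from its gene. In particular, 8 ISP1 transposon entries hold the same values in every library and are 1 measurement, but each was counted as a gene in the main counts.

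The labels name 12 samples, with 3 replicates in each of 4 groups. The table as analysed has 11 columns, all matched to samples by name, and red replicate 3 was not analysed here. The tests had been planned for 12 samples and were run on 11, with red at n = 2. The table lists 3174 genes by symbol or locus tag, 1808 of them by tag alone, with no product, position or length. Of these, 117 were at 0 FPKM in all libraries (70 tRNA, 15 rRNA and 32 other genes) and 11 more had a mean under 1 FPKM, which left 3046 for testing. A gene table of another strain was not used. The table gives no read counts, and the common step of 4 genes of low expression, chosen after their values were seen, was 2.7 to 10.6 FPKM (tolerance 0.03 steps), so a value of a few FPKM can rest on single fragments.

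Values were transformed as log2(FPKM + 1). All 11 libraries were fitted in limma 3.58.1 (R 4.3.3) with group as the only term and an empirical Bayes prior with an intensity trend. A moderated F-test compared the 4 groups, and 6 moderated contrasts (2-sided) compared each LED colour with no LED and the colours with each other. P-values were adjusted by Benjamini-Hochberg over the tested genes of each comparison, and a gene was called at an adjusted p under 0.05. A further count required an absolute log2 difference of at least 1, which is 2-fold on this scale. Fold differences in the text are ratios of mean FPKM. Shared calls between colours were set beside independent lists and beside 100 simulations of 3 unchanged groups against the same controls.

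The groups, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule takes, for each colour against no LED, the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 FPKM and no overlap between the libraries of both groups, and the 5 largest of each between colours. It adds up to 4 tested members of each list with the smallest p. Genes without a symbol were passed over and counted: 1 rise and 9 falls in blue, 4 and 6 in green, 2 and 18 in red, 1 and 2 between blue and green, 1 and 1 between blue and red, and 3 and 2 between green and red. Names of the form orf with a number were treated as having no symbol, a choice made after seeing the table. Other genes named in the report, such as the members of a list that moved against its direction and *recA*, were chosen after their values were seen.

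Of 26 gene lists, 22 had members: heat shock and protein quality control, oxidative stress and thiol redox, DNA repair and SOS response, ribosomal proteins, glycolysis and lactate, PTS sugar uptake, F1F0 ATP synthase, fatty acid synthesis, purine synthesis, pyrimidine synthesis, amino acid synthesis, riboflavin and flavin, plantaricin, prophage, capsule and exopolysaccharide, cell wall and teichoic acid, metal transport, peptide and amino acid transport, peptidases, compatible solutes and bile, malate, citrate and pyruvate metabolism, and cell division and chromosome replication. The 4 others (aminoacyl-tRNA synthetases, transposases, regulatory pairs of sensor kinase and response regulator, and the share of rRNA and tRNA) were defined by product names, which the table does not give, and have no result. The amino acid list, matched by symbol, also took in some aminoacyl-tRNA synthetases, a permease and regulators, the purine list the regulator *purR*, and *ftsH* stands in both the heat shock and the cell division list. Lists with at least 4 tested members were tested by camera in limma with its preset correlation of 0.01, with adjustment over the lists of a comparison, and again with a correlation estimated from the data. Of 132 list results 65 were called with the preset correlation. For 63 of these fry, which asks whether a list's own genes move one way, gave a p under 0.05. In blue against no LED, fry also passed this limit for most of the lists that camera did not call. Among them were DNA repair and SOS response, PTS sugar uptake, and malate, citrate and pyruvate metabolism. Since fry does not set a list against the other genes, its result adds no weight to the camera calls. In 8 list results the median, the mean and the test differed in sign, and none of these 8 was called.

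The procedure was tested on simulated data. A single set was simulated with 200 changed genes among 3046 in 11 libraries. The contrast of blue with no LED recovered 70.2% of genes changed by a log2 difference of 0.5, 98.5% at 1 and 98.5% at 2. It also called 17 unchanged genes (8.72% of calls), a share above the adjusted p limit of 0.05. In the data 1731 genes were called in this contrast, far more than were changed here, so these shares need not hold there. A list of 25 genes shifted by 0.5 was called and 0 of 20 unchanged lists were. Genes were simulated independently of each other, whereas the estimated correlations of the real lists ran from 0.0231 to 0.409. The simulation thus cannot give the rate of false list calls where the genes of a list move together.

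Alternatives changed a single choice at a time: a pseudocount of 0.1 or 10, no filter or a minimum mean of 10 FPKM, rescaling each library to a common total over the tested genes, median-of-ratios scaling, quantile normalization, a prior without a trend, only the samples of the groups compared, the replicate number as a block, an adjusted p limit of 0.01 for shared calls, and each library left out in turn. The labels give the groups the same replicate numbers and do not say what a number marks. In deviations from the group means, every same-number pair correlated above every other pair only for blue and no LED. There same-number pairs lay at 0.108 to 0.220 and the others at -0.181 to 0.0515. With 3 libraries per group such a match can also arise by chance, so a true pairing is not established. Different-number pairs of green ran from -0.293 to 0.412 with blue and from -0.183 to 0.266 with no LED. Both were highest for green 2, with blue 1 and with no LED 1. A block by number cannot take up a match across numbers, and no block for such a match was fitted. A fit of the 6 libraries of blue and no LED with the number as a block was added after seeing the data. Counting entries with identical values once, trimming the amino acid list of its synthetases, permease and regulators, and parting the heat shock list by operon were added after seeing the data. No library was doubted, so none was removed beyond the planned omissions.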

Results

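RNA sequencing measured the transcripts of *Lactiplantibacillus plantarum* WCFS1, a lactic acid bacterium, after exposure to light of different colours. Cultures in MRS, a rich medium for lactobacilli, were held at 30 °C for 12 h and lit for about 10 min by a blue (470 nm), green (525 nm) or red (630 nm) LED placed 1 cm away. Cultures without LED served as the control. The series asks which genes differ in expression between these wavelengths. Values were analysed for 11 libraries, with 3 each for no LED, blue and green and 2 for red. The third red sample was not analysed here. Expression was given as FPKM for 3174 genes, of which 3046 had a mean of at least 1 FPKM and were tested. Total FPKM per library lay between 1960419 and 2065841 and the median of the tested genes between 102.9 and 112.3 FPKM. The 10 highest genes took 17.6% to 18.1% of all FPKM in the 3 libraries without LED and 18.3% to 20.4% in the 8 lit ones. Read counts are not in the table, so the sequencing depth behind each value is unknown.

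Light of every colour was followed by a transcriptome apart from that of the unlit cultures. Of the 3046 genes, 2013 differed among the 4 groups (66.1%, limma F-test, adjusted p under 0.05). On the first principal component, which held 47.3% of the variance, the unlit libraries lay between -17.0 and -14.6, red at -9.00 and -8.03, green between 3.57 and 6.17, and blue between 13.8 and 19.7. The second component (16.5%) put the red libraries lowest, at -15.7 and -10.7. Across genes, which are not independent replicates, libraries of the same group correlated at 0.990 to 0.994. The median correlation with unlit libraries was 0.970 for blue, 0.982 for green and 0.983 for red. Adjusted p-values measure the spread between these libraries only, since the labels do not say whether replicates are separate cultures. Differences below are on the scale of log2(FPKM + 1), and levels are mean FPKM ± SD.

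**Figure D1:**
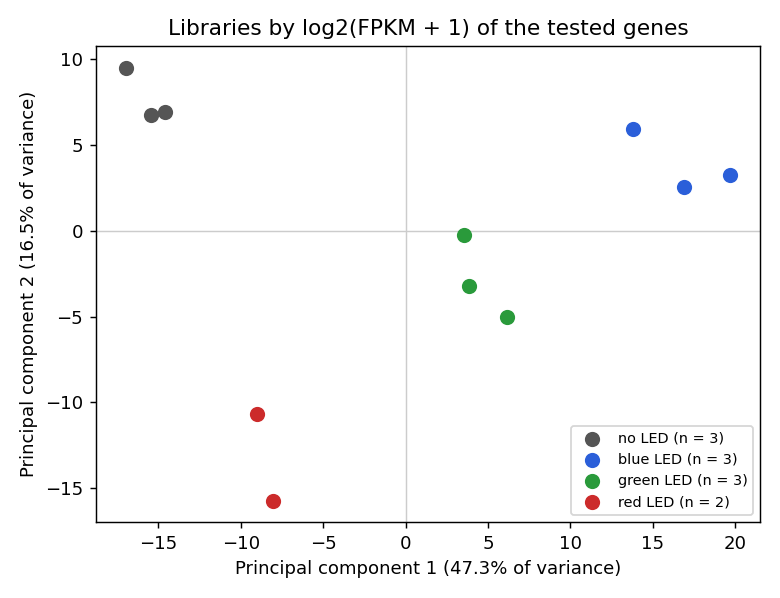
Principal components 1 and 2 of log2(FPKM + 1) over the 3046 tested genes, with 1 point per library coloured by group. Along component 1 the unlit libraries lie lowest and the 3 blue libraries highest, from 13.8 to 19.7.

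The comparison of blue with no LED asks what blue light changes. Among genes with a symbol, those for chaperones and proteases made up most of the largest rises. *hsp1*, a small heat shock protein, went from 103 ± 4.72 FPKM without LED to 1597 ± 229 under blue (n = 3 each), a 15.6-fold difference. *groEL*, the chaperonin, rose 9.79-fold to 4133 ± 393 FPKM, and *clpB*, a protein disaggregase, 7.54-fold to 892 ± 95.3 (n = 3). Most of the largest falls among genes with a symbol were in fatty acid synthesis, where *fabI*, the enoyl reductase, dropped from 501 ± 40.2 to 44.6 ± 3.95 FPKM (n = 3 each).

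Of the 22 genes for heat shock and protein quality control, 16 were higher in blue, 4 lower and 2 not called (20 called when adjusted over the list alone), with a median log2 difference of 1.32. Besides the genes above, *grpE* (log2 2.80), *dnaK* (2.71) and *groES* (2.53), all chaperone genes, rose, as did *hrcA* (2.57), the repressor of the chaperone operons, and *clpE* (2.45), a Clp ATPase. The 4 lower genes were *hslU* (-0.64), *hslV* (-0.34), *hsp2* (-0.30) and *tig* (-0.24). As a list they were higher than other genes (limma camera, adjusted p = 6.49e-06), but not when the correlation between genes was estimated from the data (adjusted p = 0.304 with an estimated correlation). Genes for oxidative stress and thiol redox were 19 higher, 10 lower and 6 not called out of 35, and the list as a whole did not pass (camera adjusted p = 0.0712). Its strongest members included *gshR2* (log2 1.85), a glutathione reductase, *msrA2* (1.61), a methionine sulfoxide reductase, and *pox2* (1.53), a pyruvate oxidase.

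**Figure D2:**
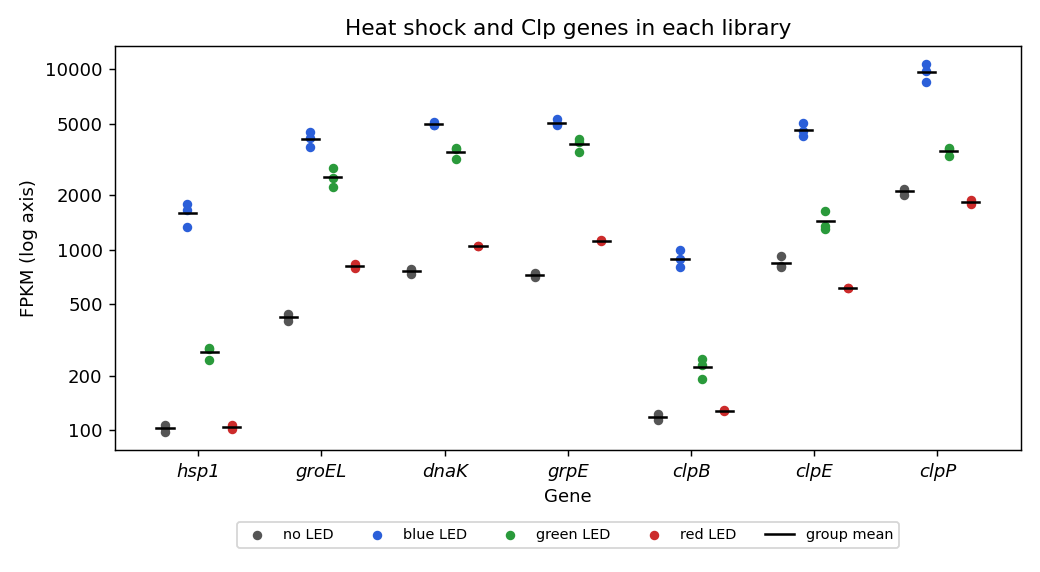
FPKM of 7 chaperone and protease genes on a log axis, with 1 point per library and a bar at each group mean. In blue *hsp1* averages 1597 FPKM against 103 without LED, 271 in green and 104 in red.

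Fatty acid synthesis moved down. Of its 21 genes, 14 were lower in blue, 2 higher and 5 not called (17 called when adjusted over the list alone), with a median log2 difference of -0.87 (camera adjusted p = 0.000125; adjusted p = 0.377 with an estimated correlation). *accA2* (-3.35), *accD2* (-3.13), *accC2* (-2.86) and *accB2* (-2.39), which encode acetyl-CoA carboxylase subunits, fell with *fabZ2* (-2.28) and *fabF* (-1.93). The 12 genes listed together from *fabZ1* to *fabI* fell further along the order of the table, with a slope of -0.28 log2 per gene, from -0.60 at *fabZ1* to -3.46 at *fabI*, and only *fabZ2* fell less than the gene before it. The 2 higher genes, *fabG2* (0.45) and *accD1* (0.14), stand elsewhere in the table.

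**Figure D3:**
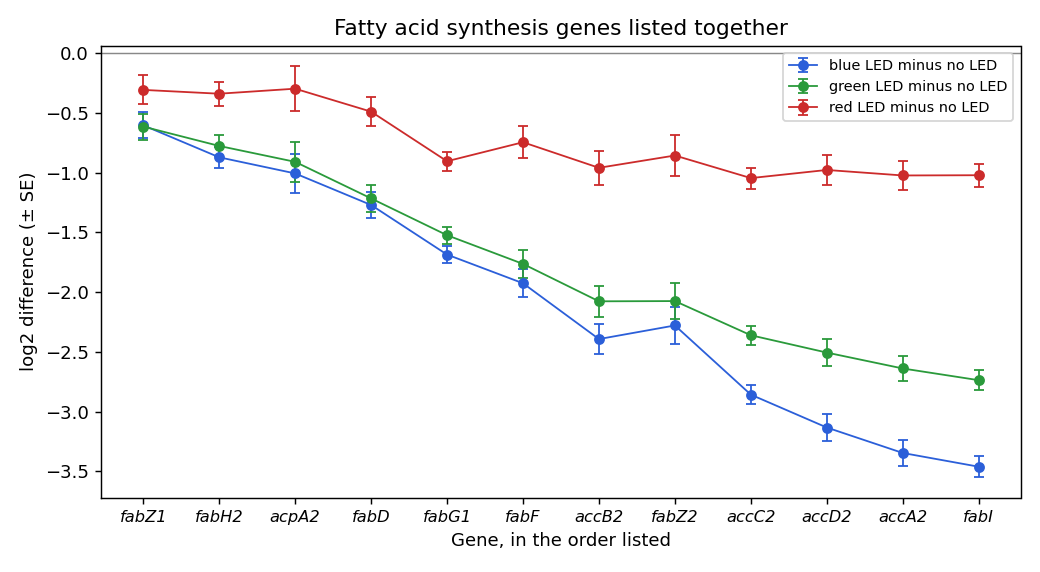
Log2 difference from no LED (± SE) of the 12 fatty acid synthesis genes listed together, in the order of the table, under each LED colour. From the first gene to the last, values go from -0.60 to -3.46 in blue, from -0.62 to -2.74 in green and from -0.31 to -1.02 in red.

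Nucleotide synthesis moved in opposite directions. Of 16 pyrimidine genes, 13 were higher in blue and none lower (14 called when adjusted over the list alone), with a median log2 difference of 1.06 (camera adjusted p = 5.16e-05; adjusted p = 0.304 with an estimated correlation). *pyrF*, the orotidine phosphate decarboxylase, rose from 14.4 ± 1.08 to 69.7 ± 4.37 FPKM (n = 3 each), and *pyrE* (log2 2.18), *pyrAB* (1.96) and *pyrD* (1.96) rose with it. Of 17 purine genes, 11 were lower and none higher (11 when adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.000568; adjusted p = 0.304 with an estimated correlation). *purA* (-1.37), the adenylosuccinate synthetase, *purR* (-1.12), the regulator, and *purB* (-0.96) fell the most.

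Cell envelope genes fell as well: 28 of 42 for cell wall and teichoic acid were lower and 6 higher (34 when adjusted over the list alone), with a median of -0.32 (camera adjusted p = 5.77e-05; adjusted p = 0.334 with an estimated correlation). *dacB* (log2 -1.15), a carboxypeptidase of the cell wall, *tagH* (-1.0), part of the teichoic acid exporter, and *pbp2x* (-0.73), a penicillin-binding protein, were among them. The 6 higher genes were *murB*, *tagE2*, *tagE3*, *tagE4*, *tagE5* and *tagE6*. Of 36 genes for cell division and chromosome replication, 18 were lower and 5 higher (24 when adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.0354; adjusted p = 0.430 with an estimated correlation). *mreB1* (-0.85), a cell shape protein, and *minD* (-0.72), a division site protein, fell, whereas *ftsH* (0.92), a membrane protease, rose. This list no longer passed with a minimum mean of 10 FPKM (adjusted p = 0.0572), after quantile normalization (adjusted p = 0.193) or with the replicate number as a block in a fit of these 6 libraries alone (adjusted p = 0.0521). Of 7 genes for compatible solutes and bile, 6 were higher and none lower (6 when adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.00336; adjusted p = 0.304 with an estimated correlation). They were led by *choQ* (0.97) and *choS* (0.64) of a choline transporter.

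The other lists were not called in blue, although single genes were. Metal transport had 10 of 16 genes lower and 3 higher (camera adjusted p = 0.0578), and peptide and amino acid transport had 9 of 16 higher and 3 lower (adjusted p = 0.0578), with *glnQ3* at a log2 difference of 1.79. Capsule and exopolysaccharide genes were 18 lower and 9 higher of 43 (adjusted p = 0.0739), with *cps3J* at -1.43. Amino acid synthesis genes were 22 higher and 9 lower of 70 (adjusted p = 0.0890), led by *argF* (1.42), and prophage genes 24 lower and 7 higher of 132 (adjusted p = 0.125). For riboflavin and flavin 2 of 5 were higher (adjusted p = 0.353), for DNA repair and SOS response 15 of 36 higher and 7 lower (adjusted p = 0.356), and for PTS sugar uptake 17 of 63 lower and 7 higher (adjusted p = 0.387). *recA*, the recombinase, stood at 770 ± 25.9 FPKM without LED and 766 ± 21.5 in blue (n = 3 each, limma adjusted p = 0.890). Plantaricin, the bacteriocin genes, had 5 of 22 lower and 2 higher (adjusted p = 0.396). Glycolysis and lactate had 6 higher and 6 lower of 21, and malate, citrate and pyruvate metabolism 8 higher and 10 lower of 26 (adjusted p = 0.492 for both). None of the 8 genes for the F1F0 ATP synthase was called by limma (0 at an unadjusted p under 0.05; list adjusted p = 0.492). Peptidases had 5 of 20 higher and 6 lower (adjusted p = 0.609), and ribosomal proteins 3 of 54 higher and 3 lower (adjusted p = 0.673).

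Across all genes, 1731 of 3046 differed between blue and no LED, 881 higher and 850 lower, and 218 of them by at least 2-fold, 143 higher and 75 lower. Further large changes were the rises of *dsdA* (log2 3.25), a D-serine dehydratase, and *arsD2* (2.50), of an arsenic resistance operon, and the falls of *drrB* (-2.06), *larA* (-1.73), a lactate racemase, and *guaC* (-1.72), a GMP reductase. With a pseudocount of 10 in place of 1 the 2-fold count was 145. Median-of-ratios scaling gave 863 higher and 893 lower. Camera called 7 of the 22 lists here, and up to 8 when the same 6 libraries were split in other ways. Those splits still hold part of the difference between the groups, so their counts are no baseline without a light effect.

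The comparison of green with no LED asks the same of green light. The chaperone genes led again among genes with a symbol. *groEL* rose from 422 ± 17.2 to 2523 ± 293 FPKM (n = 3 each), 5.98-fold, followed by *grpE* (5.29-fold), *groES* (4.87-fold), *dnaK* (4.57-fold) and *hrcA* (4.55-fold). *fabI* fell to 74.3 ± 6.12 FPKM, 0.148 of its unlit mean (n = 3).

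Of the 22 heat shock genes, 14 were higher in green and 2 lower (17 called when adjusted over the list alone), with a median log2 difference of 0.55 (camera adjusted p = 8.86e-06; adjusted p = 0.242 with an estimated correlation). The 2 lower genes were *hslU* and *tig*. Oxidative stress and thiol redox had 22 of 35 higher and 5 lower (29 when adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.000467; adjusted p = 0.242 with an estimated correlation). *gshR2* (1.56), *pox2* (1.46) and *msrA2* (1.2) rose here too. Fatty acid synthesis had 12 of 21 lower and 1 higher (13 when adjusted over the list alone), with a median of -0.78 (camera adjusted p = 2.96e-05; adjusted p = 0.291 with an estimated correlation). The falls included *accA2* (-2.64), *accD2* (-2.51), *accC2* (-2.36), *accB2* (-2.08), *fabZ2* (-2.07) and *fabF* (-1.76), and the rise was of *fabG2* (0.43). Purine synthesis had 12 of 17 lower and none higher (13 when adjusted over the list alone), with a median of -0.36 (camera adjusted p = 2.96e-05; adjusted p = 0.242 with an estimated correlation), among them *purA* (-1.67) and *purB* (-1.13). Pyrimidine synthesis had 11 of 16 higher and none lower (11 when adjusted over the list alone), with a median of 0.52 (camera adjusted p = 0.000442; adjusted p = 0.291 with an estimated correlation). *pyrG*, the CTP synthase, rose by 1.2 and *pyrF* by 1.10.

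In the cell envelope, 27 of 42 genes for cell wall and teichoic acid were lower in green and 4 higher (31 when adjusted over the list alone), with a median of -0.28 (camera adjusted p = 8.86e-06; adjusted p = 0.242 with an estimated correlation). *dacB* (-0.97), *tagH* (-0.76) and *dltD* (-0.70), of teichoic acid alanylation, fell, while *alr*, *tagE2*, *tagE3* and *tagE5* rose. Cell division and chromosome replication had 18 of 36 lower and 3 higher (21 when adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.00946; adjusted p = 0.334 with an estimated correlation). *minD* (-0.57) and *mreB1* (-0.62) fell, *ftsH*, *parC* and *parE* rose, and the list did not pass after quantile normalization (adjusted p = 0.111). Compatible solutes and bile had 6 of 7 higher and none lower (7 when adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.00312; adjusted p = 0.242 with an estimated correlation). Peptide and amino acid transport had 7 of 16 higher and 2 lower (10 when adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.0214; adjusted p = 0.291 with an estimated correlation), led by *glnQ3* (1.62) and *glnPH2* (1.33) of a glutamine transporter. The 13 remaining lists were not called, with adjusted p between 0.111 and 0.881.

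Green and no LED differed in 1311 genes, 645 higher and 666 lower, and in 82 by at least 2-fold, 43 higher and 39 lower. *dsdA* (log2 2.20), *arsD2* (2.02), *arsA* (1.91) and *arsB* (1.90) were among the largest rises, and *drrB* (-2.10) and *guaC* (-1.82) among the largest falls.

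The comparison of red with no LED, with 2 red libraries against 3, asks the same of red light. *cblB*, *cysE* and *cbs*, genes of cysteine and methionine metabolism, rose 8.49-fold, 7.71-fold and 6.73-fold. *cblB* went from 84.0 ± 4.89 FPKM (n = 3) to 713 ± 77.5 (n = 2). *oppA*, the binding protein of an oligopeptide transporter, rose 4.49-fold to 303 ± 10.2 FPKM (n = 2). *purA* fell to 119 ± 2.67 FPKM (n = 2), 0.319 of its unlit mean of 373 ± 57.4 (n = 3).

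**Figure D4:**
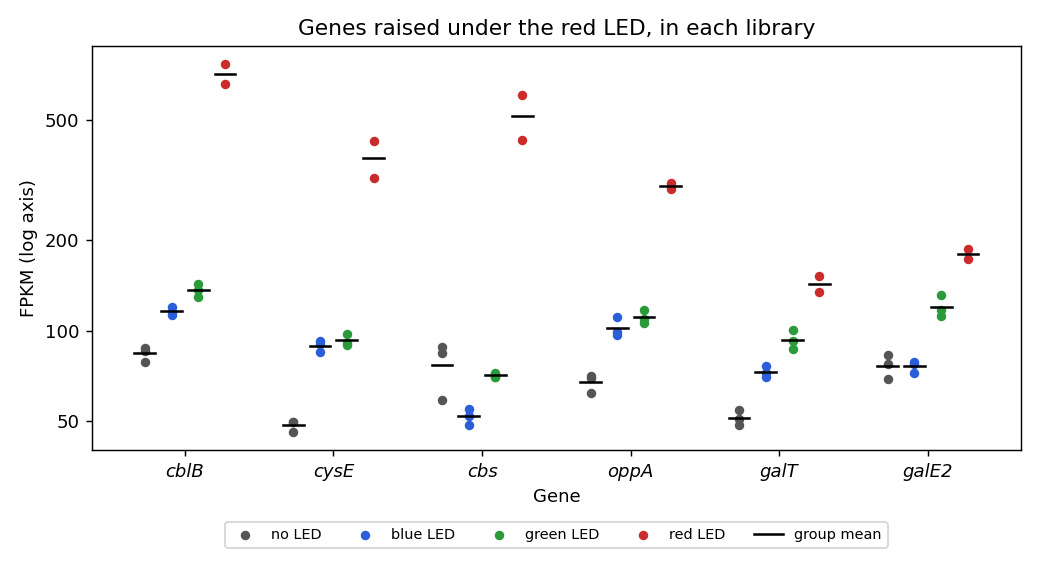
FPKM of 6 genes raised under the red LED on a log axis, with 1 point per library and a bar at each group mean. *cblB* averages 713 FPKM in red against 84.0 without LED, 116 in blue and 136 in green.

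Malate, citrate and pyruvate metabolism had 16 of 26 genes higher in red and 1 lower (17 called when adjusted over the list alone), with a median log2 difference of 0.55. This call held with either correlation (camera adjusted p = 5.43e-08; adjusted p = 0.0257 with an estimated correlation). *citP* (1.12), a citrate transporter, *fum* (0.85), the fumarase, *pflB* (0.71), pyruvate formate-lyase, and *pdhA* (0.60), of pyruvate dehydrogenase, rose, and *als* fell. PTS sugar uptake had 26 of 63 higher and 5 lower (33 when adjusted over the list alone), with a median of 0.22 (camera adjusted p = 8.85e-05; adjusted p = 0.113 with an estimated correlation), including *pts35A* (1.44), *pts29C* (0.89) and *pts6C* (0.83). Glycolysis and lactate had 10 of 21 higher and 1 lower (11 when adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.00262; adjusted p = 0.220 with an estimated correlation). *ldhL2*, a lactate dehydrogenase, rose by 1.02 and *pgm7* was the lower gene. The F1F0 ATP synthase had 7 of 8 genes higher and none lower (7 when adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.00164; adjusted p = 0.220 with an estimated correlation), such as *atpG* (0.26) and *atpD* (0.23).

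Peptide and amino acid transport had 10 of 16 higher in red and 3 lower (13 when adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.000581; adjusted p = 0.195 with an estimated correlation). After *oppA*, *glnQ3* (1.78) and *glnPH2* (1.43) rose the most, and *glnQ2*, *glnM* and *glnP1* fell. Pyrimidine synthesis had 9 of 16 higher and none lower (11 when adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.000925; adjusted p = 0.362 with an estimated correlation), with *pyrG* at 0.73. Capsule and exopolysaccharide genes were 14 higher and 7 lower of 43 (21 when adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.00598; adjusted p = 0.407 with an estimated correlation). *galE2*, a UDP-glucose epimerase, rose by 1.23 and *cps3I* fell by 0.48. Riboflavin and flavin had 3 of 5 higher and none lower (4 when adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.0101; adjusted p = 0.368 with an estimated correlation). Fatty acid synthesis had 11 of 21 lower and 1 higher (13 when adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.00161; adjusted p = 0.407 with an estimated correlation). *accC2* (-1.05), *accA2* (-1.02), *fabI* (-1.02) and *accD2* (-0.98) led it and *fabG2* was the higher gene. Cell wall and teichoic acid had 21 of 42 lower and 1, *alr*, higher (22 when adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.00120; adjusted p = 0.368 with an estimated correlation), with *tagG* at -0.82.

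The 12 lists left were not called in red, with adjusted p between 0.104 and 0.927. Among them, heat shock had 6 of 22 genes higher and 5 lower (camera adjusted p = 0.269), with *groEL* at a log2 difference of 0.94 and *clpC* at -0.43. Oxidative stress and thiol redox had 8 of 35 higher and 10 lower (adjusted p = 0.582). *trxA1* (-0.88) and *trxB* (-0.74), the thioredoxin pair, fell and *nox5* (0.69), an NADH oxidase, rose.

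Red and no LED differed in 1178 genes, 462 higher and 716 lower, and in 59 by at least 2-fold, 31 higher and 28 lower. *galT* (log2 1.46), of galactose use, and *dsdA* (1.28) rose, and *drrB* (-1.60), *guaC* (-1.60), *drrA* (-1.14), *tkt3* (-1.07), a transketolase, and *purB* (-1.0) fell. Without red replicate 1 the count was 692, and with a pseudocount of 10 the 2-fold count was 29. The excess of lower genes shrank to 522 higher and 625 lower after median-of-ratios scaling and to 570 and 581 after quantile normalization. It also depended on the red library: the median log2 difference of all genes, -0.0442 in the main fit, was -0.0132 without red replicate 1 and -0.073 without red replicate 2.

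**Figure D5:**
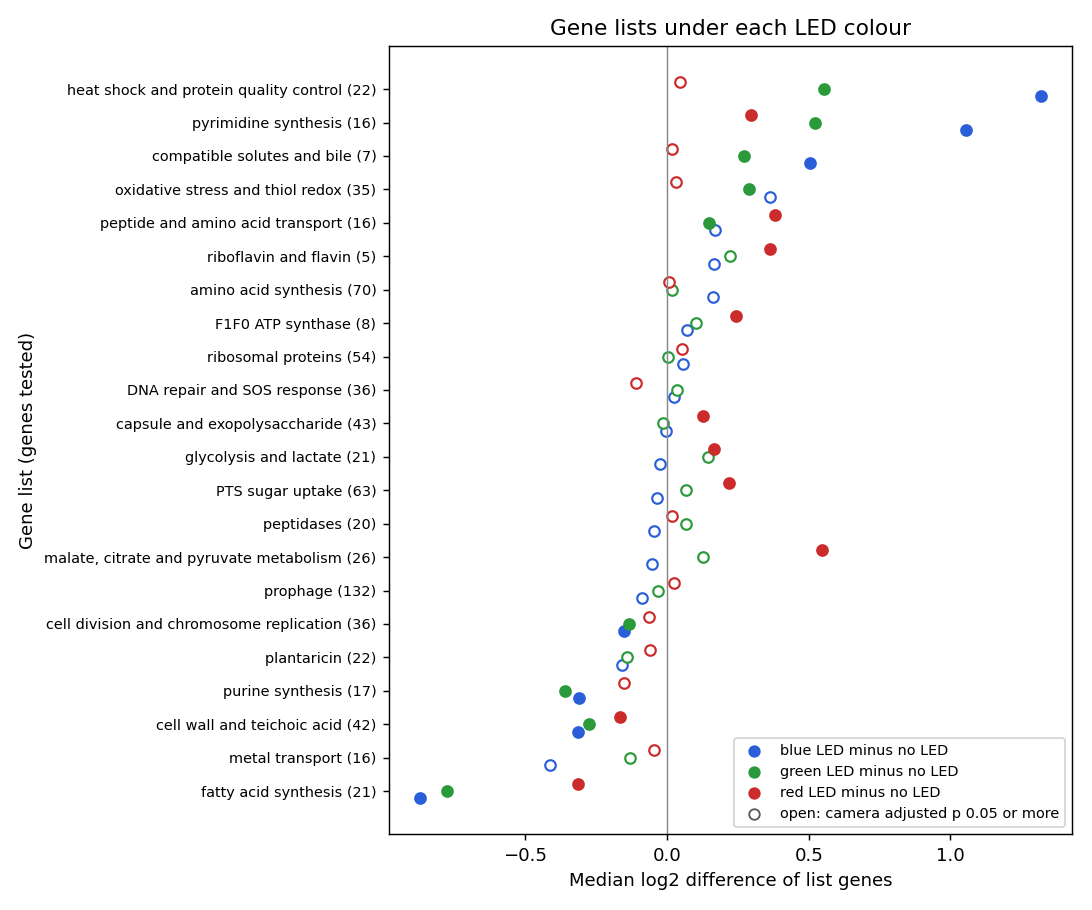
Median log2 difference from no LED of the tested genes of each of the 22 lists, under each LED colour, with filled points where camera with its preset correlation gave an adjusted p under 0.05. Heat shock has medians of 1.32 in blue, 0.55 in green and 0.04 in red.

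The colours were also compared with each other. The sample details used here give a wavelength, a time and a distance for each LED, but no light intensity. Differences between colours may therefore also reflect the light dose, which cannot be told apart from wavelength. Heat shock and Clp genes were among the largest rises of blue over green. *hsp1* averaged 1597 ± 229 FPKM in blue and 271 ± 21.7 in green (n = 3 each), a 5.90-fold difference. *clpB* was 4.0-fold higher, *clpE* 3.22-fold, *lepA2* 2.81-fold and *clpP*, the Clp protease subunit, 2.75-fold. Lower in blue were *pts35B* (log2 -1.40), *cspC* (-1.07), a cold shock protein, *pts35A* (-1.06), and *mdxE* (-1.05) and *mdxF* (-0.94) of a maltodextrin transporter.

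Between blue and green, 13 of 22 heat shock genes were higher in blue and 1, *hslU*, lower (16 called when adjusted over the list alone; camera adjusted p = 1.80e-05; adjusted p = 0.197 with an estimated correlation). Pyrimidine synthesis had 10 of 16 higher and none lower (10 when adjusted over the list alone; camera adjusted p = 0.000102; adjusted p = 0.197 with an estimated correlation), and compatible solutes and bile 5 of 7 higher and none lower (6 when adjusted over the list alone; camera adjusted p = 0.00749; adjusted p = 0.197 with an estimated correlation). Lists lower in blue were capsule and exopolysaccharide, metal transport, PTS sugar uptake, glycolysis and lactate, malate, citrate and pyruvate metabolism, fatty acid synthesis, peptidases, and prophage. Their camera adjusted p ran from 0.000141 to 0.0423, and from 0.197 to 0.528 with an estimated correlation. The call of the peptidases was lost with a minimum mean of 10 FPKM (adjusted p = 0.0528) and without green replicate 2 (0.0542). That of the prophage genes was lost after median-of-ratios scaling (adjusted p = 0.0739), without blue replicate 2 (0.124) and without green replicate 2 (0.145). In all, 874 genes differed, 483 higher and 391 lower in blue, and 41 by at least 2-fold, 35 higher and 6 lower. Without blue replicate 3 there were 540, and with a pseudocount of 10 the 2-fold count was 25. The excess of higher genes was not kept after quantile normalization, with 432 higher and 475 lower.

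The largest differences between blue and red, among genes with a symbol, were in the same protease and chaperone genes, in cysteine and methionine metabolism and in fatty acid synthesis. *hsp1* was 15.3-fold higher in blue than in red (104 ± 4.16 FPKM, n = 2), *clpE* 7.53-fold, *clpB* 6.95-fold, *clpP* 5.27-fold and *groEL* 5.09-fold. *cbs* averaged 51.9 ± 3.26 FPKM in blue (n = 3) and 519 ± 127 in red (n = 2), and *cblB* (log2 -2.60), *fabI* (-2.44), *accA2* (-2.32) and *accD2* (-2.16) were also lower in blue.

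Of the 22 lists, 15 were called between blue and red. Higher in blue were heat shock, with 17 of 22 genes higher and 3 lower (20 called when adjusted over the list alone), oxidative stress and thiol redox, with 19 of 35 higher and 10 lower (30 when adjusted over the list alone), pyrimidine synthesis, and compatible solutes and bile. Their camera adjusted p ran from 8.51e-07 to 0.0370, and from 0.190 to 0.334 with an estimated correlation. The 11 lists lower in blue included malate, citrate and pyruvate metabolism, with 15 of 26 genes lower and 3 higher (18 when adjusted over the list alone), PTS sugar uptake, with 31 of 63 lower and 4 higher (35 when adjusted over the list alone), and capsule and exopolysaccharide, with 22 of 43 lower and 1 higher (23 when adjusted over the list alone). The others were fatty acid synthesis, purine synthesis, glycolysis and lactate, cell wall and teichoic acid, metal transport, the F1F0 ATP synthase, cell division and chromosome replication, and prophage. Camera adjusted p of the 11 ran from 2.20e-06 to 0.0353, and from 0.106 to 0.343 with an estimated correlation. Without red replicate 1 the calls of the ATP synthase (adjusted p = 0.0560), cell division (0.0591) and prophage (0.0546) lists were lost, and that of the ATP synthase also without blue replicate 1 (0.0510) and after quantile normalization (0.0991). Blue and red differed in 1541 genes, 872 higher and 669 lower in blue, and in 202 by at least 2-fold, 136 higher and 66 lower, a 2-fold count that was 133 with a pseudocount of 10. Here too scaling turned the excess, to 783 higher and 795 lower after median-of-ratios scaling and 738 and 841 after quantile normalization.

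Between green and red, arsenic resistance and chaperone genes were higher in green. *arsA* was 3.45-fold higher (297 ± 25.6 FPKM in green, n = 3, and 86.2 ± 5.96 in red, n = 2), *grpE* 3.42-fold, *dnaK* 3.31-fold, *groES* 3.17-fold and *groEL* 3.10-fold. *cbs* (log2 -2.83), *cblB* (-2.38), *cysE* (-1.99), *fabI* (-1.72) and *accA2* (-1.62) were lower in green.

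Malate, citrate and pyruvate metabolism was lower in green than in red in 15 of 26 genes and higher in none (16 called when adjusted over the list alone), and this call held with either correlation (camera adjusted p = 1.01e-07; adjusted p = 0.0319 with an estimated correlation). Heat shock had 17 of 22 genes higher in green and none lower (18 when adjusted over the list alone; camera adjusted p = 8.54e-10; adjusted p = 0.137 with an estimated correlation). Oxidative stress and thiol redox, compatible solutes and bile, and DNA repair and SOS response were also higher in green (camera adjusted p from 0.000368 to 0.0228, and from 0.137 to 0.394 with an estimated correlation). Lower in green were also fatty acid synthesis, purine synthesis, capsule and exopolysaccharide, PTS sugar uptake, cell wall and teichoic acid, glycolysis and lactate, the F1F0 ATP synthase, and cell division and chromosome replication (camera adjusted p from 3.73e-06 to 0.0472, and from 0.137 to 0.418 with an estimated correlation). Quantile normalization ended the calls of DNA repair (adjusted p = 0.122), glycolysis (0.132) and the ATP synthase (0.132), the last of which was also lost without red replicate 1 (0.0558). The call of cell division was lost after rescaling each library to a common total (adjusted p = 0.0626) and without any of blue replicates 2 (0.0516) and 3 (0.0548), green replicates 1 (0.0751) and 2 (0.0756) and red replicate 1 (0.108). Green and red differed in 742 genes, 447 higher and 295 lower in green, and in 52 by at least 2-fold, 38 higher and 14 lower. Without red replicate 1 the count was 455, the share of higher genes rose from 60.2% to 73.8% without red replicate 2, and quantile normalization gave 398 higher and 415 lower.

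Many genes were called in the same direction under more than 1 colour. Blue and green shared 1093 genes, 536 higher and 557 lower, where independent lists of these sizes would share 187 and 186. Blue and red shared 645, 240 higher and 405 lower (134 and 200 if independent), and green and red 729, 289 higher and 440 lower (97.8 and 157 if independent). At an adjusted p under 0.01 the last pairs shared 380 and 438, and without red replicate 1 they shared 410 and 482. Chaperone genes *groEL*, *grpE*, *dnaK* and *hrcA* were higher, and *fabI*, *accA2*, *purA*, *purB*, *drrB* and *guaC* lower, under all 3 colours. Of the 143 genes at least 2-fold higher in blue, 129 were also called higher in green and 53 in red, and of the 75 at least 2-fold lower, 69 were also called lower in green and 63 in red. A direct test put 120 of the 143 higher in blue than in green and 137 higher than in red, and 45 and 64 of the 75 lower. These genes were chosen for a large difference in the same blue libraries, which favours a larger difference in blue. Across genes the log2 differences from no LED correlated at 0.851 for blue and green, 0.450 for blue and red and 0.628 for green and red. Because the same 3 unlit libraries stand in every comparison, 100 simulations with no light effect gave mean correlations of 0.482, 0.439 and 0.435. They gave a mean of 0 shared calls for each pair, since almost no gene can be called where none was changed. That count is therefore no baseline for the shared calls above. Covariances were 0.222, 0.110 and 0.113, against 0.0134, 0.0137 and 0.0140 in the simulations. The simulations drew every library independently, with the spread within groups as fitted over all groups. They argue against independent spread of that size among the unlit libraries as the main source of the observed covariances. An offset common to the 3 unlit libraries was not simulated, so nothing follows about it from these values. The 3 unlit libraries cannot be split into separate control sets of 2, so part of the shared calls may still come from the shared controls, which was not measured. The sample details used here also record no sham exposure of the unlit cultures. Any handling common to the lit cultures alone thus cannot be told apart from light in the shared calls.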

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

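The counts of opposite calls and the tests of scaling were planned, while the tests of warming, of RNA loss, of shared reads and of copy number were chosen only after the results were seen.

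Some genes were called in opposite directions against no LED under different colours, with the difference itself called by limma. Between blue and red there were 178 such genes, 101 higher in blue and lower in red and 77 the reverse. The first kind included *trxA1*, *trxB*, *gpo*, *gshA*, *msrA2*, *ctsR*, *clpC*, *clpE* and *choS*, and the second *pdhA*, *pdhB*, *pdhC*, *pdhD*, *pflA*, *pflB*, *fum*, *pck*, *ldhL2*, *nox5*, *mdxE* and *mdxF*. Between green and red there were 55, of which 52 were higher in green and lower in red, and between blue and green 21, of which 18 were lower in blue and higher in green.

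The number of calls was also counted in every split of the 6 libraries of a comparison into 3 and 3. The 10 splits are too few for a share under 0.05. For genes, 1 split, the real one, reached the real count in each case: 1731 against a highest other of 0 for blue and no LED, 1311 against 0 for green and no LED, and 874 against 1 for blue and green. For lists, 3 splits, the real one included, reached the 7 calls of blue and no LED (highest other 8), 1 reached the 9 of green and no LED (highest other 7), and 1 the 11 of blue and green (highest other 7). Among the 4 splits of blue and no LED that part every same-number pair, the highest other counts were 0 genes and 8 lists. Every other split keeps 2 libraries of each group together and mixes both groups on each side, so it holds part of the difference between the groups. That difference then also counts as spread within a side, which keeps gene calls low where many genes differ. The low gene counts of the other splits were therefore to be foreseen, and no conclusion on chance is drawn from them.

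Heat shock genes were higher in blue, with a median log2 difference of 1.32 over 22 genes. Scaling of FPKM between libraries is argued against as the cause, since the median was 1.31 after median-of-ratios scaling. Warming of the cultures by the LED may also raise these genes, and the cold shock genes *cspL*, *cspC* and *cspP* were lower in blue, with a median of -1.39. In green *cspL* (-0.86) and *cspP* (-0.62) fell, *cspC* was not called, and the heat shock list had a median of 0.55. In red *cspL* (-0.93) and *cspP* (-0.39) fell too, while the heat shock list had a median of 0.04. That median hides 2 sets, chosen after their values were seen. The red mean was 0.59 over *hrcA*, *grpE*, *dnaK*, *dnaJ*, *groES* and *groEL*, and -0.071 over *clpB*, *clpE*, *clpP*, *hsp1* and *hsp3*. The labels give 30 °C for lit and unlit cultures and no measured temperature of the lit ones, so warming and a response to blue light as such, which was not tested, cannot be told apart.

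The 12 fatty acid genes listed together fell in blue by -0.28 log2 per place in the table, and against the unlit mean the slopes were -0.30 to -0.26 in the blue libraries, -0.23 to -0.19 in green and -0.079 and -0.073 in red, with -0.0070 to 0.0070 as the spread of the unlit libraries around that mean. Loss of RNA toward the end of long transcripts is argued against, since the lowest slope among 9 other runs of genes listed together was -0.044. The direction of these runs was taken from general knowledge and not from the table, but in either direction 8 of the 9 had slopes of no more than 0.079 in size, and only the pyrimidine run, at 0.28, was as steep as the fatty acid run. Reads shared with other copies of the same enzymes are argued against too, since the slope over *fabD*, *fabF* and *fabI*, whose symbols carry no copy number, was -0.27. A candidate explanation is an early stop or a faster decay of this transcript in light, which was not tested.

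The last 43 genes of the table, which include *tra* genes of conjugation, *ars* genes of arsenic resistance and *rep* genes of plasmid replication, were higher in blue, with 40 called higher and 3 not called, and medians of 1.48 in blue, 0.69 in green and 0.10 in red. Scaling between libraries is argued against, since the median was 1.47 after median-of-ratios scaling. A higher copy number of the element as the whole cause is argued against, since 26 of the 43 genes lay over 3 standard errors from the median, with medians of 1.86 for 10 *tra*, 2.09 for 5 *ars* and 0.23 for 2 *rep* genes. That test replaced an earlier version, which counted genes not called higher (3 of 43) and left the matter undecided. A partial change in copy number together with separate regulation of the *ars* and *tra* genes may remain and was not tested.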

How the results depend on the processing

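Among the 326 values of genes named by the rule and the list results, no called one changed direction under any alternative; other genes named were not rerun. Counts of genes called among the 4 groups and in each comparison stayed within 1.5 times their value under every change of pseudocount, filter, scaling, prior, sample set and replicate block; with the block in all groups the F-test called 1988 genes and the contrasts 1721, 1298, 1152, 868, 1477 and 727. In blue and no LED, same-number libraries correlated at 0.108 to 0.220. The block in a fit of these 6 libraries alone gave 1627 genes and 6 lists. It ended the calls of cell division (camera adjusted p = 0.0521), *rpmH* (limma adjusted p = 0.0603) and *ribA* (0.0519). No other call of a list or of a gene named by the rule changed with it. In the other pairs of groups same-number correlations ran from -0.293 to 0.0508, and 1 of the 11 libraries correlated best with its own number. Green libraries correlated with blue and unlit libraries of other numbers at up to 0.412 and 0.266, a match that the block by number does not cover. Leaving out single libraries gave 692 to 1156 genes for red and no LED, 540 to 1015 for blue and green, 455 to 848 for green and red, 410 to 643 shared calls for blue and red and 482 to 727 for green and red. Where a group kept 1 library, it was assumed to vary like the other groups. Fewer samples may lower the counts, but they also depended on which library was left out. Blue against green had 293 genes higher and 247 lower without blue replicate 3, and 400 and 350 without blue replicate 1. The cause was not tested. At an adjusted p under 0.01, blue and red shared 380 calls and green and red 438, as a stricter limit must give fewer. With a pseudocount of 10 the 2-fold counts were 145 for blue, 29 for red, 25 between blue and green and 133 between blue and red, since it shrinks differences of genes with low FPKM. With an estimated correlation the lists called were 0 in blue, 0 in green, 1 in red, 0 between blue and green, 0 between blue and red and 1 between green and red, since the estimate exceeds the preset 0.01. The median difference of all genes stayed within 0.1 of 0 in every scaling. Quantile normalization moved the share of higher genes in red from 39.2% to 49.5% and between green and red from 60.2% to 49.0%; the cause was not tested. The larger of the higher and lower counts changed side under some scaling in every comparison but red and no LED. Blue and red went from 872 higher and 669 lower to 783 and 795 (median-of-ratios) and 738 and 841 (quantile), blue and green from 483 and 391 to 432 and 475 (quantile), and blue and no LED from 881 and 850 to 863 and 893 (median-of-ratios). Medians of lists changed sign under scaling 12 times, never in a called list. Uncalled lists became called 20 times in alternatives chosen beforehand. Peptide and amino acid transport in blue passed after rescaling (adjusted p = 0.0480), quantile normalization (0.0295) and 3 omissions (0.0447 to 0.0478), and metal transport and prophage in blue after quantile normalization (0.0295 each). Quantile normalization also called purines (0.0447) and peptidases (0.0105) in red, and a minimum mean of 10 FPKM PTS in green (0.0344) and amino acid synthesis in red (0.0495). Prophage between green and red passed in 4 alternatives (0.0132 to 0.0426), and the others were omissions of single libraries. Without its synthetases, permease and regulators, an alternative chosen after seeing the data, the amino acid list was called in blue (adjusted p = 0.0362) and between blue and green (0.0131). Of the 326 values, 312 were called, and 34 of these lost the call in some alternative. The read depth is unknown, so how far it limits genes of low FPKM was not measured.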

Other observations

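The genes below were chosen after their values were seen, as was the test of the chaperone and protease sets.

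Genes of phosphate uptake, *pstA* to *pstE*, were higher in blue by log2 differences of 1.51 to 1.95, in green by 0.70 to 1.04 and in red by 0.53 to 0.90. *pstA* went from 13.7 ± 1.07 FPKM without LED to 55.8 ± 1.15 in blue (n = 3 each). The ammonium transporter gene *amtB* was higher under each colour, by 1.13 in blue, 0.94 in green and 1.10 in red. *nrdD* and *nrdG*, of the anaerobic ribonucleotide reductase, were higher in blue (1.26 and 1.06), green (1.06 and 0.87) and red (0.47 and 0.26). Lactate racemase genes *larA*, *larB* and *larC1* were lower in blue (-1.73, -1.15 and -1.46) and green (-0.97, -0.72 and -0.93). In red *larA* (-0.28) and *larC1* (-0.37) were lower, and *larB* was not called (limma adjusted p = 0.842).

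*galT*, *galK* and *galE2*, of galactose use, were higher in red by 1.46, 1.03 and 1.23, each also called against blue and against green. In green they were higher by 0.84, 0.51 and 0.64, and in blue only *galT* was (0.50). Their regulator gene *galR* was higher under each colour, by 0.72 in blue, 0.74 in green and 1.15 in red. *malT* and *mapA*, of maltose use, were higher in red by 1.07 and 1.06, in green by 0.71 and 0.57 and in blue by 0.58 and 0.48. *mdxE* and *mdxF*, of a maltodextrin transporter, were higher in red (0.92 and 1.00) and green (0.27 and 0.22) and lower in blue (-0.77 and -0.72). The ISP1 entries, which hold 1 measurement, were higher in blue by 1.05, in green by 0.53 and in red by 0.28. In the main counts each entry stands as a gene, also among the 143 genes at least 2-fold higher in blue. With entries of identical values counted once, 873 genes were higher and 848 lower in blue than without LED, against 881 and 850.

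The mean log2 difference from no LED was 2.61 in blue, 2.16 in green and 0.59 in red over *hrcA*, *grpE*, *dnaK*, *dnaJ*, *groES* and *groEL*, and 2.64, 0.96 and -0.071 over *clpB*, *clpE*, *clpP*, *hsp1* and *hsp3*. The gap between these sets differed by 1.23 between blue and green, with -0.45 to -0.26 in the blue libraries, -1.62 to -1.55 in green and -1.08 and -1.02 in red. The exact permutation test of blue and green (2-sided) gave p = 0.1, the smallest that 20 arrangements allow, so it could not pass 0.05. The 5 genes of the second set include the largest differences between blue and green and were picked after these were seen, so the gap does not stand for all *clp* and *hsp* genes. The 5 others, *clpC*, *clpL*, *clpX*, *hsp2* and *hsp33*, had a mean of 0.10 between blue and green, against 0.45 for the set with *hrcA*, and of these 5 only *clpC* was called (0.73).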
